A study of Mus musculus with 6 samples.

How the data were processed

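Single-cell RNA-seq was made from tumours grown in the pancreas of 6 C57BL/6J mice from KPC pancreatic cancer cells. Per the labels, 3 mice were treated with IgG and 3 with an antibody against mouse VSIG4, at doses and times not given, and tumours were collected 11 days after inoculation. Each mouse gave 1 library, and the mouse was the replicate.

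The authors deposited 1 sparse matrix per library, and the deposited values are UMI counts per gene and cell barcode. PISA 1.0 wrote the matrices, per the file headers. STAR and Seurat 4.11 were used as well, per the submitters' processing notes, which do not say for which steps. The tool settings, genome build and gene annotation are not given in the sources used here. Totals ranged from 26606234 to 47221033 UMIs per library. Every deposited barcode held at least 1000 UMIs, so cells had been selected before deposit. Across libraries, 20468 genes were listed in every library and 29781 in any. A gene missing from a library was counted as 0 there.

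The cell filters, class markers, gene lists, tests, named-gene rule and first set of alternatives were fixed before the data were examined. Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. The doublet caller Scrublet, run per library in scanpy with an expected rate of 0.06, marked 0 of 47603 cells. The caller was therefore taken not to have worked, no doublets were removed, and removal of the 6% of cells with the highest score in each library was added as an alternative. Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for plots. Counts per cell were scaled to 10000 and log-transformed. Leiden clusters were built at resolution 1.0 from 3000 variable genes chosen per library, 40 principal components and 20 neighbours, with a random seed of 0.

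Clusters were named from fixed markers of 24 classes, so each class name stands for cells like that type. The name was the class whose markers had the highest mean log2 ratio over the median cluster, computed on CPM plus 20. A cluster stayed unnamed with fewer than 3 raised markers, with more markers of another class among its 10 leading genes, or with UMI counts under 1/3 of the library median and no marker of its own among those genes. A further rule was set after the data were seen. Clusters whose median cell had more than 15% of its UMIs in genes spanning more than 100 kb were called nucleus-like and left unnamed. Gene spans came from the GENCODE mouse reference annotation, matched by symbol for 88.3% of genes and 97.0% of UMIs, and served this measure alone. Libraries were then called few-kind or many-kind, with less or more than 1% nucleus-like cells. T and NK cells, and monocyte/macrophages, were clustered again and named from markers of 11 subsets. Here ratios were taken over the lower quartile of sub-clusters. Sub-clusters also stayed unnamed with 2 or more leading genes of another lineage, or with 2 close best matches and fewer than 2 own markers leading, a rule set after the data were seen. These clusters split by library, so they were first integrated with Seurat 5.3.0 (reciprocal PCA, 30 dimensions).

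For gene tests, UMI counts were summed per library and class, for classes with at least 20 cells in each library. In R 4.3.3, edgeR 4.0.16 was run with TMM scaling, filterByExpr, robust glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment within each class at a false discovery rate of 0.05. For 40 gene lists, limma 3.58.1 camera was run with a preset correlation of 0.01 on lists with at least 5 tested members, adjusted over lists within each class. Cell numbers per class were tested with edgeR for classes averaging at least 10 cells per library, with total cells as offset, and within the T/NK and monocyte/macrophage compartments for subsets. Single values per library were compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. Shares of cells with a Vsig4 UMI were taken after each cell was thinned to 1000 UMIs. Ratios of UMI counts carry an exact binomial interval, which covers counting error alone.

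The text names genes by a fixed rule. It covers a fixed set of genes given in full and, per class, genes past the false discovery rate with at least 20 CPM and no overlap between groups, up to 12 per direction in the 6 main classes and 5 elsewhere. Where none passed, the 5 genes with the smallest p and at least 20 CPM are given as not passing. Up to 4 members with the smallest p are taken from each called list. Gene models named Gm or Rik, immunoglobulin and T cell receptor segments and pseudogenes were counted but not named. A gene or value outside the rule is said to be so.

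The tests were run on simulated counts with the real means and library sizes and 200 changed genes. In monocyte/macrophages (13040 genes), edgeR recovered 35.8% of genes changed by 2-fold and 84.8% of those changed by 4-fold, with 5 false calls. The figures were 42% and 94.9% in T cells (10859 genes, 23 false calls), 34.4% and 89.9% in tumour cells (12011 genes, 16 false calls), and 13.8% and 80.2% in fibroblasts (9595 genes, 11 false calls). DESeq2 made 17, 31, 28 and 16 false calls in these 4 classes. Of 5 lists shifted by 1.5-fold, camera called 5 in monocyte/macrophages, 5 in T cells, 4 in tumour cells and 4 in fibroblasts. False list calls numbered 0, 0, 1 and 1 of 26. With an estimated correlation, 5, 2, 0 and 1 of the 5 lists were called. Simulated genes were drawn independently of one another. The list results therefore cannot show how the preset correlation performs on genes that vary together, as in the real data. The subset abundance test recovered 88 of 100 simulated 4-fold changes, with 15 false calls of 500.

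The alternatives tried were other size factors (RLE), DESeq2 1.42.0, no count filter, a replicate block, leaving out each library, stricter cell filters (1000 UMIs and 10% mitochondrial UMIs), resolution 2.0, equal cell numbers per library, camera with an estimated correlation, limma's fry, limma on logit shares, TMM scaling of cell numbers, and other denominators and thinning depths. Added after the data were seen were removal of high doublet scores, library kind as a covariate, and separate fits of the few-kind and the many-kind libraries. Those separate fits have 1 library on one side, which is assumed to vary like the others, and the difference between the 2 kinds of fit was not tested. Vsig4, which filterByExpr left out, was put back into the fit after the data were seen.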

Results

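Gene expression in single cells was measured in orthotopic pancreatic tumours, grown in the pancreas of C57BL/6J mice from KPC cells, a mouse pancreatic cancer line. The groups were 3 IgG-treated mice (IgG 1, 2 and 3) and 3 mice treated with an antibody against VSIG4 (anti-VSIG4 1, 2 and 3), sampled 11 days after inoculation. The IgG libraries held 26606234, 41504714 and 47221033 UMIs in 7170, 8215 and 9566 barcodes. The anti-VSIG4 libraries held 41823906, 28499280 and 39629304 UMIs in 9527, 6518 and 6798 barcodes. Of 47794 barcodes, 47603 passed the filters (24856 IgG and 22747 anti-VSIG4), with median UMIs per kept cell between 2127 in IgG 1 and 2703 in anti-VSIG4 3. Group values below are means over 3 libraries per group ± SD. The error after an edgeR log2 change, anti-VSIG4 over IgG, is an approximate standard error. It is the size of the change divided by the square root of the F statistic of its test, and can be too small at low counts.

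The cells formed 28 clusters. Neutrophils were the most numerous class (16113 cells), followed by monocyte/macrophages (11222), T cells (6148), tumour/epithelial cells (2655), type 2 conventional dendritic cells (cDC2, 1287), NK cells (1170), fibroblasts (893), migratory dendritic cells (619) and endothelial cells (453). Another 3 clusters, with 5976 cells, were rich in UMIs from long genes, as nuclei are, and were left unnamed. These nucleus-like cells made up 0.349%, 17.2% and 43.4% of IgG 1, 2 and 3 and 0.348%, 0.231% and 5.40% of anti-VSIG4 1, 2 and 3 (exact two-sided permutation p = 0.2). IgG 1, anti-VSIG4 1 and anti-VSIG4 2 therefore formed a few-kind of library, and IgG 2, IgG 3 and anti-VSIG4 3 a many-kind, so that library kind and treatment overlapped in part. Haemoglobin transcripts, from red cells, took 0.0234 ± 0.0236% of UMIs in IgG and 0.0955 ± 0.0124% in anti-VSIG4 libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). Acinar enzyme transcripts took 0.0416%, 0.336% and 0.142% in IgG and 0.0593%, 0.0478% and 0.0296% in anti-VSIG4 libraries. Over the sum of all kept cells, 15 of 15 acinar transcripts were lower in anti-VSIG4 (camera adjusted p = 2.50e-09, 0.674 with an estimated correlation). In few-kind libraries alone they were higher (adjusted p = 0.0182), and in many-kind libraries lower (adjusted p = 8.57e-25).

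The comparison asked what treatment with the anti-VSIG4 antibody changed in the tumour and its immune cells, beginning with the target. Vsig4 encodes a macrophage receptor for complement fragments that restrains T cells. In monocyte/macrophages, 36 Vsig4 UMIs were counted in the IgG libraries (17, 8 and 11, of 30943760 UMIs) and 3 in the anti-VSIG4 libraries (1 in each, of 43961765 UMIs). The ratio of IgG to anti-VSIG4 was 17.05, with a counting interval of 5.387 to 86.53. That interval takes UMIs as independent, although some cells held several, so it is too narrow. Mean levels were 1.23 ± 0.546 and 0.0718 ± 0.0205 CPM, with every IgG library above every anti-VSIG4 library. The log2 change was -3.95 ± 0.67 with edgeR, and -4.22 in few-kind and -3.89 in many-kind libraries. Adjusted over the list alone, the fixed set of 11 genes for these cells, Vsig4 passed (adjusted p = 0.00187, 1 of 11 genes), but adjusted over all 13041 genes it did not (edgeR adjusted p = 0.36, with 0.00522 to 1 over the alternatives and 0.0657 with DESeq2). The share of monocyte/macrophages with a Vsig4 UMI was 0.432 ± 0.165% in IgG and 0.0484 ± 0.00712% in anti-VSIG4 libraries (exact two-sided permutation p = 0.1). After each cell was thinned to 1000 UMIs it was 0.103 ± 0.178% and 0.0484 ± 0.00712% (exact permutation p = 1.0). At that depth 7, 0 and 0 IgG cells and 1 cell of each anti-VSIG4 library held a UMI, so the IgG mean came from IgG 1 alone, and without IgG 1 it was 0. As background, 0 of 6148 T cells held a Vsig4 UMI, which allows a share of up to 0.0488%, and 1 UMI each was found in neutrophils, tumour cells and cDC2 and 2 in migratory dendritic cells, all in IgG libraries. Fibroblasts of anti-VSIG4 1 held 1 UMI, at 0.957 CPM, against 0.0657 CPM in the monocyte/macrophages of that library. Median depths were 4554 UMIs in monocyte/macrophages, 3025.5 in T cells and 1575 in neutrophils. Most of the Vsig4 UMIs lay in 2 sub-clusters of monocyte/macrophages, a resident-type one led by Ccl8, Cbr2, Lyve1 and Folr2 and an unnamed one led by Saa3, Marco and Cd5l. There, 18 of 659 IgG cells (10, 3 and 5 in IgG 1, 2 and 3) and 2 of 458 anti-VSIG4 cells held Vsig4. The source differed between IgG libraries. In IgG 1, 2 and 3 the resident-type sub-cluster gave 10, 2 and 0 of these cells and the unnamed one 0, 1 and 5. These 18 IgG cells held 32 Vsig4 UMIs. The 2 sub-clusters were chosen for at least 2 Vsig4-positive cells in the IgG libraries, so the choice itself favours an IgG excess there.

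**Figure D1:**
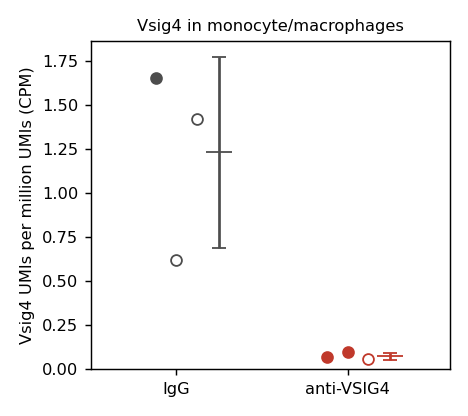
Vsig4 level in monocyte/macrophages (vertical axis, CPM) in the IgG and anti-VSIG4 groups. Each point is 1 library, filled for the few-kind and open for the many-kind, and bars give the mean ± SD over 3 libraries. IgG libraries lie between 0.618 and 1.66 and anti-VSIG4 libraries between 0.0550 and 0.0947.

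By camera with the preset correlation, monocyte/macrophages of the anti-VSIG4 tumours had higher proliferation genes and lower interferon, glycolysis and hypoxia genes as groups, with small shifts per gene. Of 39 lists 14 were called, and 4 of the 10 splits of the 6 libraries, the real one included, gave as many or more. Over the 6 main classes the highest count in another split was 17 to 26 lists. List calls alone therefore do not separate treatment from other groupings of the libraries. Proliferation genes rose together, with all 26 tested members higher and a median log2 change of 0.31 (camera adjusted p = 3.12e-07, 0.598 with an estimated correlation). Ube2c, a cyclin-degrading ubiquitin enzyme, went from 23.3 ± 2.83 to 33.8 ± 5.37 CPM, and Mcm4, a part of the replicative helicase, from 16.2 ± 2.39 to 21.8 ± 2.86 CPM. The group was higher in few-kind (adjusted p = 3.98e-04) and in many-kind libraries (adjusted p = 0.047). Glycolytic enzymes fell together, with 16 of 16 lower and a median of -0.26 (adjusted p = 5.36e-05, 0.598 with an estimated correlation). Gpi1, which turns glucose-6-phosphate into fructose-6-phosphate, was at 874 ± 249 and 586 ± 35.8 CPM, and Hk1, a hexokinase, at 65.6 ± 11.98 and 46.9 ± 3.04 CPM. It passed in many-kind libraries (adjusted p = 3.70e-05) and did not pass in few-kind ones (adjusted p = 0.879). Hypoxia genes were lower by a median of -0.21 (13 of 16, adjusted p = 2.49e-04, 0.666 with an estimated correlation), with P4ha2, a collagen-modifying hydroxylase, at 23.1 ± 7.85 and 11.2 ± 2.69 CPM. In few-kind libraries alone the hypoxia group was higher (adjusted p = 0.0354).

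Type I interferon genes (19 of 24 lower, median -0.25) and interferon-gamma genes (25 of 27 lower, median -0.23) fell in these cells, each with an adjusted p of 2.49e-04, or 0.666 with an estimated correlation. Irf7, a transcription factor that amplifies the interferon response, was at 129 ± 17.1 CPM in IgG and 89.8 ± 19.1 CPM in anti-VSIG4 libraries. Ifih1, a sensor of viral RNA, was at 29.4 ± 5.22 and 19.3 ± 3.50 CPM. Both calls were lost without IgG 1 (adjusted p = 0.22 for type I and 0.194 for interferon-gamma genes) or without anti-VSIG4 2 (0.206 and 0.882), and neither passed in many-kind libraries (0.208 and 0.205). MHC class I presentation genes fell as well (15 of 15 lower, median -0.24, adjusted p = 5.55e-04, 0.598 with an estimated correlation), a call lost without anti-VSIG4 2 (adjusted p = 0.0864). Neutrophil granule genes rose (8 of 10 higher, median 0.54, adjusted p = 8.74e-06, 0.321 with an estimated correlation). Among them was Lcn2, an iron-sequestering antibacterial protein, whose adjusted p over the list alone was 0.00267. Transcripts of neutrophils were also higher in this class (7 of 7, median 0.69, adjusted p = 5.55e-04, 0.666 with an estimated correlation). The latter call was lost without IgG 3 (adjusted p = 0.084) or anti-VSIG4 1 (0.213), and haemoglobin took 0.00367% and 0.0231% of the UMIs of the class (exact permutation p = 0.1). M1-type (adjusted p = 0.548), M2-type (0.546), complement (0.161), phagocytic receptor (0.193) and lipid-associated (0.189) genes did not pass.

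No single gene passed in monocyte/macrophages with edgeR (0 of 13040, with 515 at an unadjusted p under 0.05), while DESeq2 called 23, 9 higher and 14 lower. The smallest p-values belonged to Lcn2, at 11.9 ± 1.99 CPM in IgG and 29.8 ± 8.69 CPM in anti-VSIG4 libraries (log2 change 1.33 ± 0.24), and Thbd, the anticoagulant receptor thrombomodulin, at 44.5 ± 5.24 and 80.8 ± 7.17 CPM (0.86 ± 0.16). Lcn2 levels were higher in tumour cells (132 and 314 CPM) and neutrophils (217 and 388 CPM). Whether its rise came from monocyte/macrophages was not tested. Folr2, a folate receptor of resident macrophages, was at 96.5 ± 11.6 and 48.0 ± 10.4 CPM (-1.01 ± 0.19), complement C4b at 88.0 ± 17.3 and 42.9 ± 10 CPM (-1.04 ± 0.22), and Pltp, a phospholipid transfer protein, at 263 ± 20.8 and 145 ± 27.4 CPM (-0.86 ± 0.18). Their edgeR adjusted p lay between 0.39 and 0.648, and their DESeq2 adjusted p between 0.00305 and 0.0128. Each had the same sign in both library kinds, as with C4b at -1.14 in few-kind and -1.32 in many-kind libraries. The other fixed genes of these cells did not pass, over all genes or over the list alone. They included C1qa, which starts the classical complement cascade (6882 ± 1389 and 5175 ± 1841 CPM, log2 change -0.41 ± 0.27), C3, the central complement protein (291 ± 49.2 and 262 ± 42.9 CPM), and the MHC class II gene H2-Ab1 (8083 ± 2936 and 6468 ± 2423 CPM). Among genes linked to macrophage polarization, Arg1 was at 3388 ± 1385 and 2862 ± 139 CPM, Mrc1 at 187 ± 93.3 and 191 ± 83.5, Cd163 at 5.03 ± 4.19 and 3.80 ± 2.29, Spp1 at 307 ± 133 and 434 ± 50.9, and Nos2 at 55.3 ± 23.1 and 44.9 ± 13.8. The T cell attractant Cxcl9 was at 456 ± 27.7 and 455 ± 195 CPM, and the checkpoint ligand Cd274 had a log2 change of -0.04. Groups did not overlap for 8.90% of genes, against 10% by chance. Fits within library kinds called 64 genes in few-kind and 334 in many-kind libraries, a fit with library kind as covariate called 4, and leaving out IgG 1 gave 18.

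By camera with the preset correlation, fibroblasts of the anti-VSIG4 tumours differed in several programmes. Of 39 lists 17 were called, and 3 of the 10 splits of the 6 libraries, the real one included, gave as many or more (highest 23). Genes of interferon responses, of inflammatory cancer-associated fibroblasts and of MHC class I presentation fell as groups, while contractile, myofibroblastic genes rose. Each of these 5 calls was lost with an estimated correlation. Each passed without any 1 library and in the separate fit of each library kind, which has 1 library on one side. Of 19 type I interferon genes, 18 were lower, with a median log2 change of -1.06 (camera adjusted p = 8.04e-17, 0.29 with an estimated correlation). Adjusted over the list alone, 10 of the 19 passed, and none did over all genes. Isg15, a ubiquitin-like interferon product, was at 1026 ± 99.7 CPM in IgG and 391.8 ± 147 CPM in anti-VSIG4 libraries, and Oasl1, a regulator of antiviral signalling, at 63.1 ± 13.9 and 20.1 ± 6.43 CPM. Interferon-gamma genes followed (23 of 24 lower, median -0.85, adjusted p = 6.47e-16, 0.305 with an estimated correlation, 3 adjusted over the list alone), with the interferon-induced GTPase Gbp7 at 58.5 ± 4.15 and 29.0 ± 7.40 CPM. All 15 MHC class I presentation genes were lower (median -0.56, adjusted p = 1.21e-10, 0.29 with an estimated correlation, 1 adjusted over the list alone). Of these, the nonclassical MHC gene H2-Q6 was at 74.1 ± 11.9 and 26.6 ± 5.44 CPM and the peptide transporter Tap2 at 111 ± 10.9 and 72.7 ± 5.60 CPM.

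Of 13 inflammatory fibroblast genes, 12 were lower (median -0.90, camera adjusted p = 6.47e-16, 0.29 with an estimated correlation), and 8 passed adjusted over the list alone. Clec3b, which encodes tetranectin, was at 323 ± 125 CPM in IgG and 28.2 ± 21.5 CPM in anti-VSIG4 libraries. Dpt, a matrix protein of quiescent fibroblasts, was at 545 ± 180 and 203 ± 27.4 CPM, and Has1, a hyaluronan synthase, at 373 ± 88.8 and 110 ± 56.9 CPM. All 12 myofibroblastic genes were higher (median 0.75, adjusted p = 9.39e-11, 0.29 with an estimated correlation), 5 of them adjusted over the list alone. Acta2, smooth muscle actin, was at 472 ± 188 and 1039 ± 174 CPM, Tagln, an actin-bundling protein, at 1198 ± 161 and 2483 ± 354 CPM, and Myl9, a myosin light chain, at 184 ± 46.1 and 368 ± 48.4 CPM. Acta2 and Tagln were also among the fixed markers of pericytes and smooth muscle. Fibroblasts were not clustered again. A change in the mix of fibroblast kinds, or pericytes within the class, was therefore not tested as a source of these group changes. The myofibroblastic group had an adjusted p of 0.0071 in few-kind and 1.06e-12 in many-kind libraries. Collagen transcripts did not pass (adjusted p = 0.45). Lymphocyte and monocyte chemokines fell (adjusted p = 0.0159, 0.521 with an estimated correlation), 1 of them, the monocyte attractant Ccl2, adjusted over the list alone (adjusted p = 0.0423, 1040 ± 334 and 449 ± 189 CPM). That call was lost without IgG 1 (adjusted p = 0.363), anti-VSIG4 2 (0.141) or anti-VSIG4 3 (0.249). Stress genes also fell (18 of 20 lower, median -0.46, adjusted p = 9.56e-07, 0.521 with an estimated correlation), and did not pass in many-kind libraries alone (0.149).

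In this class edgeR called 0 of 9595 genes (584 at an unadjusted p under 0.05), and DESeq2 called 38, 5 higher and 33 lower. The 5 genes with the smallest p were complement C4b (log2 change -1.59 ± 0.26, 257 ± 56.7 and 85.6 ± 21.5 CPM), H2-Q6 (-1.49 ± 0.26), the adhesion molecule Cadm3 (-1.96 ± 0.35), Oasl1 (-1.68 ± 0.31) and Lrrn4cl (-1.72 ± 0.32), all at an edgeR adjusted p of 0.282. Their DESeq2 adjusted p lay between 0.00042 and 0.0298. Fits of few-kind and many-kind libraries called 92 and 163 genes, and the fit with library kind as covariate 13. Without IgG 1, IgG 2 or anti-VSIG4 1, edgeR called 7, 2 and 1 genes. Group ranges were apart for 10.84% of genes, against 10% by chance. The fibroblasts came from 207, 141 and 228 cells in IgG and 82, 181 and 54 cells in anti-VSIG4 libraries. Mitochondrially encoded transcripts were lower (11 of 11, median -0.44, camera adjusted p = 7.65e-04, 0.521 with an estimated correlation), a call lost without IgG 1 (0.308) or anti-VSIG4 3 (0.478). Macrophage markers had a higher level in this class (median log2 change of the tested markers 0.76, 0.35 in few-kind and 0.93 in many-kind libraries).

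**Figure D2:**
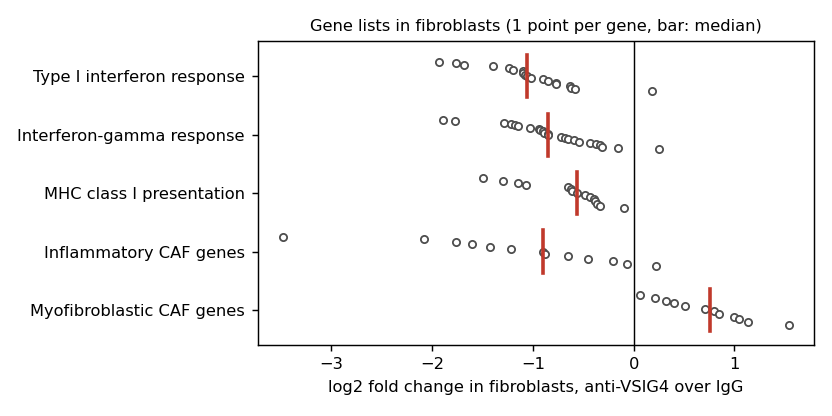
Log2 fold changes in fibroblasts, anti-VSIG4 over IgG (horizontal axis), of the tested members of 5 gene lists (vertical axis), from 3 libraries per group. Each point is 1 gene and each red bar the median of its list, which lies at -1.06 for the type I interferon list and at 0.75 for the myofibroblastic list.

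Tumour/epithelial cells also showed lower interferon-gamma and MHC class I genes. Of 27 interferon-gamma genes 25 were lower, with a median log2 change of -0.57 (camera adjusted p = 4.05e-12, 0.375 with an estimated correlation). All 15 MHC class I presentation genes were lower (median -0.41, adjusted p = 3.50e-09, 0.375 with an estimated correlation). Both groups also passed in few-kind (adjusted p = 1.93e-08 and 1.75e-04) and in many-kind libraries (5.16e-10 and 3.12e-08), and without any 1 library. Ido1, which degrades tryptophan, was at 33.2 ± 10.4 CPM in IgG and 16.2 ± 7.81 CPM in anti-VSIG4 libraries, and the peptide loaders Tap2 and Tapbp were at 72.9 ± 9.76 and 43.4 ± 10.3 CPM and at 333 ± 34.5 and 231 ± 44.8 CPM. None of the members of these 2 lists passed adjusted over the list alone. Transcripts that belong to other cells rose in the same class. Cytotoxic lymphocyte genes were higher by a median of 1.03 (12 of 12, adjusted p = 5.56e-09, 0.375 with an estimated correlation), with the chemokine Ccl5 at 75.1 ± 22.01 and 165 ± 55.0 CPM. M2-type macrophage genes were higher by 0.95 (14 of 14, adjusted p = 5.10e-08, 0.375 with an estimated correlation, 0.454 in few-kind libraries). Macrophage markers had a median of 0.78 (-0.05 in few-kind and 1.03 in many-kind libraries), and neutrophil transcripts of 0.90 (adjusted p = 1.34e-04, 0.394 with an estimated correlation), the latter call being lost without anti-VSIG4 1 (adjusted p = 0.0824). Fibroblast programmes moved here in the same direction as in fibroblasts. Myofibroblastic genes were higher (8 of 9, median 0.83, adjusted p = 3.19e-04, 0.375 with an estimated correlation, 0.725 in many-kind libraries), with Tagln at 4.18 ± 2.06 and 23.4 ± 27.1 CPM. Inflammatory fibroblast genes were lower (7 of 8, median -0.34, adjusted p = 0.0311, 0.375 with an estimated correlation), a call lost without IgG 1 (0.0814) or anti-VSIG4 3 (0.113). Signs of handling and RNA quality moved as well. Heat-shock and dissociation genes fell (13 of 20, median -0.26, adjusted p = 0.0139, 0.652 with an estimated correlation), with Hspa1a at 241 ± 148 and 113 ± 63.1 CPM, a call lost without IgG 2 (0.271), anti-VSIG4 1 (0.052) or anti-VSIG4 2 (0.933). Ribosomal protein genes rose (45 of 46, median 0.14, adjusted p = 1.27e-04, 0.53 with an estimated correlation), a call lost without IgG 3 (0.0737).

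No gene passed in tumour cells with edgeR (0 of 12011, 467 at an unadjusted p under 0.05), and DESeq2 called 4. How many of these 4 calls are false was not tested. The smallest p-values belonged to Lcn2 (132 ± 34.5 CPM in IgG and 314 ± 13.6 CPM in anti-VSIG4 libraries, log2 change 1.26 ± 0.21), the cytokine subunit gene Il23a (14.1 ± 0.972 and 38.0 ± 15.6 CPM), the MHC class I peptide editor Tapbpl (48.1 ± 7.57 and 25.8 ± 2.80 CPM), the water channel Aqp1 (58.9 ± 8.87 and 32.3 ± 3.40 CPM) and the basal keratin Krt14 (55.3 ± 13.97 and 23.6 ± 5.99 CPM), all at an adjusted p of 0.999. Lcn2 passed adjusted over the list alone, among 9 neutrophil granule genes that rose together (adjusted p = 0.00206 for Lcn2 and 1.59e-06 for the group, 0.375 with an estimated correlation, 0.0534 in few-kind libraries). Of the fixed genes 0 of 4 passed, over all genes or adjusted over the list alone. The ductal keratin Krt19 was at 2386 ± 279 and 1965 ± 142 CPM, the MHC gene H2-K1 at 1495 ± 27.7 and 1229 ± 383, the cycling marker Mki67 at 21.2 ± 1.58 and 18.8 ± 4.92, and Cd274 at 35.6 ± 23.9 and 46.9 ± 26.4. Group ranges were apart for 7.86% of genes, against 10% by chance. Few-kind and many-kind libraries gave 6 and 107 genes, and leaving out IgG 1 or IgG 2 gave 3 and 1.

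In T cells, genes of naive and memory cells rose and genes of exhaustion fell as groups in the anti-VSIG4 tumours, while cytotoxic genes did not pass (adjusted p = 0.830). Of 10 naive and memory genes 9 were higher, with a median log2 change of 0.40 (camera adjusted p = 3.13e-05, 0.334 with an estimated correlation), and 2 passed adjusted over the list alone. Il7r, the interleukin-7 receptor that keeps resting T cells alive, was at 36.7 ± 13.3 CPM in IgG and 66.8 ± 2.68 CPM in anti-VSIG4 libraries, Klf2, a factor of quiescence and recirculation, at 140 ± 35.0 and 228 ± 37.5 CPM, and the homing receptor Ccr7 at 161 ± 47.8 and 220 ± 46.0 CPM. The group passed in many-kind libraries (adjusted p = 4.80e-07) and did not pass in few-kind ones (0.907). Of 15 exhaustion genes 13 were lower (median -0.29, adjusted p = 2.16e-03, 0.334 with an estimated correlation), with the inhibitory receptors Lag3 at 82.1 ± 25.1 and 54.0 ± 17.9 CPM and Havcr2 at 26.2 ± 9.16 and 19.4 ± 5.65 CPM, and Tox, a factor of the exhausted state, at 51.0 ± 16.6 and 37.5 ± 6.96 CPM. The exhaustion group passed in few-kind (adjusted p = 0.0269) and many-kind libraries (0.0188), but not without anti-VSIG4 2 (0.0922). Proliferation genes fell (23 of 26 lower, median -0.25, adjusted p = 1.93e-04, 0.494 with an estimated correlation), a call lost without IgG 3 (0.723) or anti-VSIG4 3 (0.0635) and not passing in few-kind libraries (0.907). Activation genes (adjusted p = 0.0974) and regulatory T cell genes (0.371) did not pass. Naive-type T cells took a larger mean share of the T and NK cells in anti-VSIG4 libraries, given below, a difference that did not pass. The part of such subset shares in these group changes was not tested.

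Transcripts of myeloid cells were higher in the T cell class. All 10 MHC class II genes were higher (median 0.61, camera adjusted p = 5.53e-11, 0.334 with an estimated correlation), and 7 passed adjusted over the list alone, among them H2-Ab1 at 331 ± 84.4 and 532 ± 98.8 CPM. Complement genes rose by a median of 0.63 (14 of 16, adjusted p = 3.80e-09, 0.334 with an estimated correlation), with C1qc at 56.4 ± 18.3 and 120 ± 37.8 CPM, and all 20 NF-kB inflammatory genes were higher (median 0.64, adjusted p = 1.71e-09, 0.334 with an estimated correlation). Macrophage markers as a set had a median log2 change of 0.97 in T cells (0.70 in few-kind and 1.07 in many-kind libraries), against -0.08 in monocyte/macrophages themselves. With edgeR 0 of 10859 genes passed (405 at an unadjusted p under 0.05), and DESeq2 called 6, all higher. How many of these 6 calls are false was not tested. Among the smallest p-values were those of the activin gene Inhba (18.4 ± 0.537 and 41.2 ± 6.89 CPM, log2 change 1.17 ± 0.20), the cytokine Csf2 (15.2 ± 3.07 and 33.0 ± 8.09 CPM), fibronectin Fn1 (26.1 ± 1.81 and 56.4 ± 20.2 CPM) and the myeloid integrin Itgam (14.4 ± 4.40 and 29.96 ± 7.14 CPM), at adjusted p from 0.464 to 0.985. Of the fixed genes 0 of 8 passed, over all genes or adjusted over the list alone. The coreceptors Cd8a and Cd4 were at 292 ± 90.7 and 265 ± 42.3 CPM and at 156 ± 47.5 and 134 ± 20.4 CPM. The killing proteins Gzmb and Prf1 were at 362 ± 78.0 and 369 ± 125 CPM and at 101 ± 44.8 and 66.7 ± 26.6 CPM. Ifng was at 62.7 ± 7.93 and 51.1 ± 21.7 CPM, Foxp3, the factor of regulatory T cells, at 36.6 ± 28.2 and 47.5 ± 15.4, the checkpoint receptor Pdcd1 at 203 ± 27.5 and 176 ± 35.0, and Tcf7, of naive and stem-like cells, at 60.8 ± 15.4 and 73.4 ± 17.3. Groups did not overlap for 8.45% of genes, against 10% by chance. Few-kind and many-kind libraries gave 15 and 24 genes, and leaving out IgG 1 or IgG 2 gave 1 each. Of 39 lists 20 were called, and 13 without IgG 3.

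NK cells showed higher myeloid and inflammatory transcripts and no call for cytotoxic genes (adjusted p = 0.307). Of 32 lists 11 were called, all higher, with 18 without IgG 1. NF-kB inflammatory genes rose by a median log2 change of 0.60 (17 of 19, camera adjusted p = 3.18e-10, 0.304 with an estimated correlation). Cd14, the monocyte coreceptor for bacterial lipopolysaccharide, was at 179 ± 56.1 CPM in IgG and 427 ± 129 CPM in anti-VSIG4 libraries. MHC class II genes rose by 0.63 (7 of 8, adjusted p = 1.79e-05, 0.304 with an estimated correlation), 6 of them adjusted over the list alone, with the invariant chain gene Cd74 at 691 ± 64.2 and 1133 ± 191 CPM. Complement genes rose by 0.39 (11 of 11, adjusted p = 1.42e-05, 0.151 with an estimated correlation). These 3 groups also passed in the separate fit of each library kind. Hypoxia genes rose by 0.32 (9 of 10, adjusted p = 3.03e-03, 0.532 with an estimated correlation), with Hilpda, a lipid droplet protein, at 156 ± 33.5 and 299 ± 68.5 CPM, a call lost without IgG 3 (0.0502) or anti-VSIG4 2 (0.152). Macrophage markers had a median of 0.78 in this class (0.35 in few-kind and 0.92 in many-kind libraries), and neutrophil transcripts of 1.18 (adjusted p = 1.42e-05, 0.341 with an estimated correlation). With edgeR 0 of 5691 genes passed (289 at an unadjusted p under 0.05) and DESeq2 called 0. The 5 smallest p-values, at an adjusted p of 0.771, were those of H2-Aa, Cd14, C1qc, the survival gene Bcl2a1b (97.8 ± 22.4 and 224 ± 49.3 CPM) and Cmip (441 ± 63.8 and 243 ± 32.3 CPM). Without anti-VSIG4 3, 22 genes were called, without IgG 2 it was 2 and without IgG 1 it was 1, and few-kind and many-kind libraries gave 10 and 12. Groups did not overlap for 10.49% of genes, against 10% by chance.

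In neutrophils, Car4, a membrane-bound carbonic anhydrase, rose from 54.7 ± 2.73 CPM in IgG to 180 ± 22.7 CPM in anti-VSIG4 libraries. It was the 1 gene of 11071 past the threshold (log2 change 1.72 ± 0.17, edgeR adjusted p = 0.027), with 614 at an unadjusted p under 0.05 and 12 called by DESeq2. Its log2 change was 1.89 in few-kind and 1.5 in many-kind libraries and between 1.63 and 1.80 when 1 library was left out. The adjusted p of Car4 in Neutrophil cells then rose to 0.0546 without IgG 1, 0.253 without IgG 2, 0.321 without IgG 3, 0.18 without anti-VSIG4 1 and 0.233 without anti-VSIG4 2. Granule and maturation genes rose together (11 of 11, median 0.58, camera adjusted p = 4.81e-05, 0.553 with an estimated correlation), 3 of them adjusted over the list alone, and the group passed in the separate fit of each library kind. Cd177, a surface protein of mature neutrophils, was at 282 ± 24.1 and 530 ± 81.4 CPM, and Cybb, the catalytic part of the oxidase that makes superoxide, at 22.3 ± 2.27 and 33.0 ± 4.14 CPM. M2-type genes rose by 0.73 (15 of 15, adjusted p = 3.32e-08, 0.553 with an estimated correlation), with Arg1 at 95.3 ± 22.6 and 186 ± 74.0 CPM, and MHC class II genes by 0.76 (10 of 10, adjusted p = 5.13e-08, 0.553 with an estimated correlation). Of 15 macrophage markers 14 were also higher in this class. The M2-type and MHC class II groups may therefore hold transcripts of other cells, which was not tested. Heat-shock and dissociation genes fell (17 of 20 lower, median -0.25, adjusted p = 7.49e-04, 0.553 with an estimated correlation), 3 of them adjusted over the list alone, such as the chaperone Hspa1a at 678 ± 334 and 236 ± 77.5 CPM. The group passed in many-kind libraries (adjusted p = 1.64e-03) and did not pass in few-kind ones (0.513). Interferon-gamma genes were lower by a median of -0.21 (adjusted p = 9.79e-03, 0.637 with an estimated correlation), a call lost without IgG 1 (0.591) or anti-VSIG4 2 (0.904). Macrophage markers had a median of 0.63 in this class (0.35 in few-kind and 0.61 in many-kind libraries), and 11 of 12 mitochondrially encoded transcripts were higher (camera adjusted p = 0.0247, 0.637 with an estimated correlation), a call lost without IgG 2 (0.287) or anti-VSIG4 1 (0.999). Of 39 lists 25 were called, and 14 without anti-VSIG4 1. Groups did not overlap for 11.71% of genes, against 10% by chance, and few-kind and many-kind libraries gave 24 and 180 genes.

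Whether treatment changed the makeup of the tumours was asked from the cells per class. T cells made up 10.2 ± 4.65% of cells in IgG and 16.5 ± 7.48% in anti-VSIG4 libraries (log2 change 0.70 ± 0.62), monocyte/macrophages 20.8 ± 10.4% and 28.0 ± 3.90%, neutrophils 31.1 ± 11.7% and 36.7 ± 12.7%, tumour cells 6.16 ± 2.23% and 4.66 ± 1.18%, and fibroblasts 2.34 ± 0.586% and 1.48 ± 1.13%. With edgeR 0 classes passed (adjusted p from 0.662 to 0.886), 0 had an unadjusted p under 0.05, and limma on logit shares called 0. The smallest p was that of B cells, at 0.331% and 0.724% (log2 change 1.14 ± 0.65, edgeR adjusted p = 0.662). Without the nucleus-like cells in the denominator, the shares were 12.6 ± 3.50% and 16.8 ± 7.26% for T cells and 25.1 ± 6.31% and 28.6 ± 3.67% for monocyte/macrophages.

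Within the T and NK cells, gamma-delta T cells, lymphocytes that make interleukin-17 in many tissues, were at 0.699 ± 0.604% in IgG and 2.55 ± 0.310% in anti-VSIG4 libraries. Every anti-VSIG4 library lay above every IgG library (18, 4 and 2 cells against 36, 49 and 24), but the log2 change of 1.78 ± 0.58 did not pass (edgeR adjusted p = 0.0721, exact two-sided permutation p = 0.1). It was 0.87 in few-kind (adjusted p = 0.405) and 2.88 in many-kind libraries (0.0699), and it passed without IgG 1 (0.0020) and without anti-VSIG4 3 (0.0467), within a range of 0.0020 to 0.405 over the alternatives. Of the T and NK subsets 0 passed with edgeR, 1 had an unadjusted p under 0.05, and limma called 1. Conventional CD4 T cells were at 4.76 ± 1.41% and 8.05 ± 0.923% (adjusted p = 0.242) and naive-type T cells at 6.81 ± 2.90% and 10.9 ± 2.15%, both past the threshold without IgG 1 (0.0322 and 0.0302). NK cells were at 17.9 ± 3.38% and 12.5 ± 8.86%, a difference past the threshold without anti-VSIG4 3 (log2 change -1.28, adjusted p = 0.0467). CD8 T cells were at 39.9% and 39.3%, and regulatory T cells at 4.36% and 4.84%. Within the monocyte/macrophages 0 subsets passed with edgeR (adjusted p = 0.962), 0 had an unadjusted p under 0.05, and limma called 0. Unnamed sub-clusters did not enter this test. Among them were the one led by Saa3, Marco and Cd5l (469 IgG and 271 anti-VSIG4 cells) and one led by Ccl17 and Mgl2 (368 and 629 cells). C1q macrophages were at 18.2% and 17.7%, Spp1/Arg1 macrophages at 14.2% and 14.1%, classical monocytes at 20.7% and 22.5%, and resident-type macrophages at 3.15 ± 3.17% and 2.85 ± 1.29%, with 6.81% in IgG 1. In classical monocytes, the platelet-factor chemokine Pf4 was the 1 gene past the threshold of 7769 (125 ± 29.98 and 432 ± 159 CPM, log2 change 1.79 ± 0.27, edgeR adjusted p = 0.0402, 219 at an unadjusted p under 0.05, 3 with DESeq2). Pf4 was also a leading gene of a C1q macrophage sub-cluster, and whether its rise came from monocytes was not tested. The adjusted p of Pf4 in classical monocytes rose to 0.0819 without IgG 1, 0.177 without IgG 2, 0.361 without IgG 3 and 0.286 without anti-VSIG4 1.

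**Figure D3:**
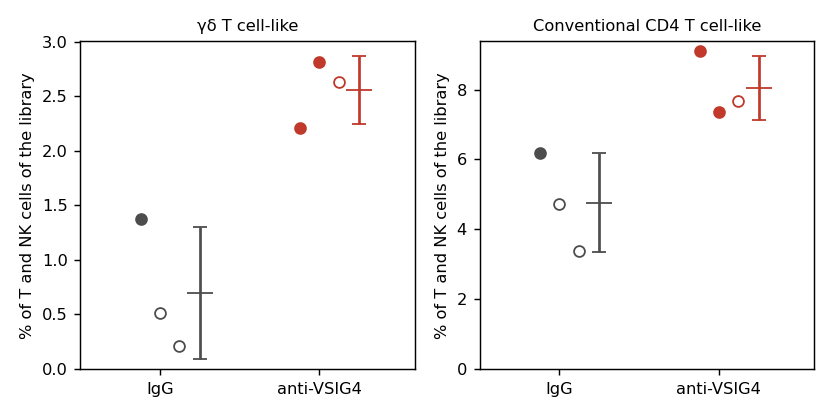
Gamma-delta T cells (left) and conventional CD4 T cells (right) as a percent of the T and NK cells of each library (vertical axes) in the IgG and anti-VSIG4 groups. Each point is 1 library, filled for the few-kind and open for the many-kind, and bars give the mean ± SD over 3 libraries; every anti-VSIG4 library lies above every IgG library in both panels.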

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

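All tests named here as within 1 library kind, with library kind as a covariate or with high doublet scores removed were chosen after the results were seen, as was keeping Vsig4 among the tested genes; the others were planned. Keeping called doublets, also planned, was void, since the caller marked 0 cells. The fall of Vsig4 in monocyte/macrophages kept its direction in every alternative run, between -2.66 with equal cell numbers per library and -4.28 without IgG replicate 2, and -3.72 without IgG replicate 1. Its adjusted p passed in 1 of them, without the count filter (log2 change -3.93 over 25208 genes, adjusted p = 0.00522, within a range of 0.00522 to 1). Thinning moved the difference in the share of cells with Vsig4, anti-VSIG4 minus IgG, from -0.0541 percentage points at 1000 UMIs to -0.244 at 2000 UMIs and -0.383 without thinning. At 2000 UMIs, 844 IgG and 1076 anti-VSIG4 cells with fewer UMIs were left out, and the cause of the move was not tested. At 36 and 3 UMIs, depth limits what can be said of this gene per cell.

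Counts of called genes depended on the tool, the filter and the libraries entered. DESeq2 called 38 genes in fibroblasts, 23 in monocyte/macrophages, 12 in neutrophils, 6 in T cells and 4 in tumour cells, where edgeR called 0, 0, 1, 0 and 0. In simulated counts DESeq2 made 16 false calls in fibroblasts, 17 in monocyte/macrophages, 31 in T cells and 28 in tumour cells. Those counts also held genes set to change, and the false calls let through grow with the number of genes called. The simulated false calls therefore cannot tell how many of the real DESeq2 calls are false. Without the count filter, edgeR called 171 in fibroblasts, 80 in T cells, 70 in neutrophils, 47 in tumour cells, 31 in monocyte/macrophages and 27 in NK cells, and in monocyte/macrophages the prior degrees of freedom went from 5.78 to 211. Library kind as a covariate gave 13 genes in fibroblasts, 9 in neutrophils, 4 in monocyte/macrophages and 4 in NK cells. Within the few-kind libraries, 92 genes were called in fibroblasts, 64 in monocyte/macrophages, 24 in neutrophils, 15 in T cells, 10 in NK cells and 6 in tumour cells. Within the many-kind libraries the counts were 163, 334, 180, 24, 12 and 107. Equal cell numbers ended the call of Car4 in neutrophils (0 genes), and removal of high doublet scores gave 1 gene in T cells. Other size factors and resolution 2.0 gave 1 gene in neutrophils and 0 in the other 5 classes, as the planned test did. Stricter cell filters removed too few cells to test anything (9528 to 9452 in IgG 3, the largest loss). Leaving out 1 library gave 0 to 7 genes in fibroblasts (7 without IgG 1), 0 to 18 in monocyte/macrophages (18 without IgG 1), 0 to 22 in NK cells (22 without anti-VSIG4 3), 0 to 1 in neutrophils (1 without anti-VSIG4 3), 0 to 1 in T cells (1 without IgG 1 or IgG 2) and 0 to 3 in tumour cells (3 without IgG 1). Except for the smaller number of genes or samples in some of these fits, the cause was not tested.

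Of 159 called lists, 1908 alternative values were computed, of which 1242 kept the call, 660 kept the direction and lost it, and 6 reversed. With an estimated correlation, and with fry, 0 lists were called in each of the 6 main classes. Within the few-kind libraries 10 lists were called in fibroblasts, 13 in neutrophils and 12 in tumour cells, against 17, 25 and 22 in all libraries. Acinar transcripts, lower in all libraries, were higher within the few-kind over all cells (adjusted p = 0.0182), in fibroblasts (0.00198), monocyte/macrophages (9.45e-12), neutrophils (5.05e-08) and T cells (6.07e-10), and so were hypoxia genes in monocyte/macrophages (0.0354). Leaving out 1 library gave 8 (without IgG 3) to 18 (without IgG 1) lists in NK cells, 13 (without IgG 3) to 25 (without IgG 1) in T cells and 14 (without anti-VSIG4 1) to 26 (without anti-VSIG4 3) in neutrophils. The cause was not tested.

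No alternative run gave a class that passed in abundance (0 in each). Among T and NK subsets, where 0 passed, 1 passed with limma on logit shares, 1 with library kind as a covariate and 1 within the many-kind libraries, and 0 to 3 when 1 library was left out (3 without IgG 1). Among monocyte/macrophage subsets 2 passed within the many-kind libraries. The cause was not tested. Of 1692 alternative values for 100 named genes, 1509 kept their side of the threshold, 164 passed where the planned test did not, 19 lost a call and 0 called values reversed, while 35 changed sign without a call. Of 405 values for 24 shares of cells, 394 kept their side and 11 newly passed, and 54 changed sign without a call.

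The replicate numbers were not taken to pair the mice, since 2 of 3 same-number pairs correlated above 0.1 in each class but the lowest correlation was -0.307 over all cells. A fit with replicate number as a block called 64 genes in fibroblasts, 22 in NK cells, 11 in neutrophils, 11 in T cells, 1 in tumour cells and 0 in monocyte/macrophages, and 1 T and NK subset. In monocyte/macrophages the correlations of same-number libraries ran from -0.239 to 0.279, and the highest between libraries of other numbers was 0.322, so that not every library correlated best with its own number. In each class examined, pairs of the same library kind correlated above 0 and pairs of different kinds below 0. The correlations thus followed library kind. Replicate numbers 1 and 3 each pair libraries of the same kind, so the block stands in part for library kind.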

Other observations

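The tests of explanations below were all chosen after the results were seen, and for the doublet test alone the prediction was written before its own value was seen. In endothelial cells, Hp, which encodes the haemoglobin scavenger haptoglobin, rose from 14.2 ± 3.66 CPM in IgG to 80.5 ± 26.9 CPM in anti-VSIG4 libraries. It was the 1 gene of 6612 past the threshold (log2 change 2.48 ± 0.36, edgeR adjusted p = 0.0181, with 323 at an unadjusted p under 0.05 and 5 with DESeq2). Hp was also a leading gene of a classical monocyte sub-cluster, and 10 of 10 tested macrophage markers were higher in this class. Whether the rise of Hp came from endothelial cells was not tested. The adjusted p of Hp in endothelial cells rose to 0.0665 without IgG 1, 0.0666 without IgG 3, 0.129 without anti-VSIG4 2 and 0.752 with high doublet scores removed, within a range of log2 changes from 2.27 to 2.74 when 1 library was left out. MHC class I presentation genes fell here too (14 of 15 lower, median -0.39, camera adjusted p = 1.31e-04, 0.533 with an estimated correlation), with the immunoproteasome gene Psmb10 at 446 ± 40.2 and 261 ± 25.4 CPM. Type I interferon genes fell (15 of 18 lower, median -0.53, adjusted p = 2.72e-05, 0.533 with an estimated correlation), a call lost without anti-VSIG4 2 (0.139). Of 13 complement genes 9 were higher and 4 lower (median 0.94, adjusted p = 1.25e-04, 0.533 with an estimated correlation), with the macrophage product C1qb at 61.7 ± 24.3 and 185 ± 44.4 CPM and the alternative-pathway factor Cfb at 97.8 ± 18.3 and 39.1 ± 4.89 CPM. Macrophage markers had a median of 1.5 in this class.

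In cDC2, which present antigen to CD4 T cells, all 23 proliferation genes were higher (median 0.67, camera adjusted p = 1.64e-14, 0.119 with an estimated correlation), and 5 passed adjusted over the list alone. The group also passed without any 1 library and in the separate fit of each library kind. Ube2c was at 35.8 ± 8.46 CPM in IgG and 76.4 ± 25.5 CPM in anti-VSIG4 libraries, and Birc5, a mitosis and survival gene, at 25.8 ± 14.3 and 56.5 ± 13.3 CPM. All 21 type I interferon genes were lower (median -0.57, adjusted p = 6.81e-08, 0.632 with an estimated correlation, 0.121 in many-kind libraries). The other lists called in this class were higher and included neutrophil transcripts, cytotoxic genes and lipid-associated macrophage genes. Gzma was at 10.8 ± 4.09 and 32.3 ± 21.3 CPM, and Apoe at 474 ± 83.8 and 831 ± 112 CPM. How far transcripts of other cells shape the cDC2 results was not tested. With edgeR 0 of 8329 genes passed, with 352 at an unadjusted p under 0.05 and 0 by DESeq2. In migratory dendritic cells, the 5 genes with the smallest p were all lower, such as the phosphodiesterase Pde4d at 490 ± 205 and 171 ± 23.2 CPM and the adhesion molecule Alcam at 123 ± 61.7 and 32.3 ± 5.55 CPM (edgeR adjusted p = 0.396, 0 of 5107 genes passed, 526 at an unadjusted p under 0.05, 14 with DESeq2). Ribosomal protein genes were higher there (46 of 46, median 0.36, adjusted p = 2.30e-07, 0.903 with an estimated correlation, 0.549 in few-kind libraries). Without IgG 1, 249 genes were called in these cells. The real split called 7 lists in cDC2 and 3 in migratory dendritic cells, against 6 to 12 and 5 to 16 in the other splits of the 6 libraries. Leaving out 1 library gave 5 (without anti-VSIG4 1) to 17 (without anti-VSIG4 3) in cDC2, and 2 (without IgG 3) to 9 (without IgG 1) in migratory dendritic cells. In plasma cells 0 of 3003 genes passed with edgeR (241 at an unadjusted p under 0.05, 10 with DESeq2, 172 without IgG 1), and the mitochondrially encoded transcripts were lower (9 of 9, median -1.37, adjusted p = 5.27e-07, 0.804 with an estimated correlation, 0.248 in few-kind libraries), with wide spreads such as mt-Co2 at 673 ± 352 and 290 ± 72.9 CPM. Extracellular matrix genes were lower in plasma cells (8 of 8, median -0.44, adjusted p = 0.0432, 0.804 with an estimated correlation), a call lost without IgG 1 (0.521), IgG 3 (0.0965), anti-VSIG4 1 (0.218) or anti-VSIG4 3 (0.593). They were higher in T cells (15 of 20, median 0.30, adjusted p = 0.0255, 0.734 with an estimated correlation), a call lost without IgG 3 (0.677) or anti-VSIG4 2 (0.275). Checkpoint ligands (adjusted p from 0.152 to 0.899), epithelial-mesenchymal transition genes (0.0513 to 0.891) and collagen transcripts (0.212 to 0.871) were called in 0 of the classes tested.

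Vsig4 transcripts were 17.05 times as abundant in the monocyte/macrophages of the IgG as of the anti-VSIG4 libraries. Fewer sequenced UMIs cannot account for this, since the anti-VSIG4 libraries held 1.42 times as many monocyte/macrophage UMIs. Fewer cells of the 2 sub-clusters that hold Vsig4 cannot account for all of it. Their pooled share changed by -0.91 ± 0.40 on the log2 scale, against -3.95 ± 0.67 for Vsig4 with edgeR and -4.15 ± 1.08 with DESeq2. That share pools the resident-type sub-cluster (190 IgG and 187 anti-VSIG4 cells) with the unnamed one (469 and 271 cells). In the unnamed one 6 IgG and 0 anti-VSIG4 cells held Vsig4. Loss of a finer group of resident-type macrophages may contribute and stays open, as 6 other resident-type markers had a median log2 change of -1.13 (SD 0.657), with Folr2 at -0.98 ± 0.20 and Timd4 at -1.76 ± 0.49 and F13a1 at -0.06. A lower transcript level per cell after treatment stays open as well and was not tested.

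Few genes passed in any class, while the split of the 6 libraries by kind called many. In monocyte/macrophages and fibroblasts 14 genes each were called in the same direction in both kinds, against 0.638 and 0.650 by chance, and 3 each in opposite directions, against 0.697 and 0.603. Since both counts lay above chance, the ratio of the 2 was taken, at 5.10 (counting interval 1.42 to 27.7) and 4.33 (1.21 to 23.5) times its chance value, which leaves open whether differences between kinds hide group differences. The 14 in monocyte/macrophages include transcripts of other cells, such as Hbb-bt of red cells, Mcpt1 of mast cells, Camp of neutrophils and 2 immunoglobulin segments, besides C4b and Lyve1, and those in fibroblasts include C4b, Clec3b, Has1, Col14a1, Oasl1 and H2-Q6, all named after their values were seen. In T cells and in tumour cells 0 genes were called in both kinds in the same direction (0.00783 and 0.00569 by chance), so the test decides nothing there. Treatment and library kind overlap in part, and each separate fit has 1 library on one side, so how far the kinds shape the pooled result stays open.

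Macrophage transcripts were higher in the anti-VSIG4 libraries in classes that should lack most of them. The marker Ly6c2 was also a leading gene of CD8 T sub-clusters, so T cells carried part of the set themselves. The median log2 change of the tested markers was above 0 in 6 of 6 non-myeloid classes, from 0.56 in plasma cells to 1.5 in endothelial cells, and T cells with a marker UMI at 1000 UMIs went from 67.8 ± 16.7% to 87.3 ± 5.80%. The T cell median was 1.01 times as large without the cells of high doublet score (0.97 with and 0.99 without them). The removed T cells did carry more marker UMIs (3.32 ± 0.254 against 1.57 ± 0.547 in IgG). The score came from the caller that marked 0 cells, so this bears on high-score cells alone and not on doublets at large. The T and NK cells also kept 2 unnamed sub-clusters with leading myeloid genes, 527 cells led by S100a9 and S100a8 and 118 led by H2-Ab1 and Arg1. More free macrophage RNA stays open, since the lowest median within 1 library kind, -0.0512 in tumour cells of few-kind libraries (0.70 in T cells), lay within the spread of its markers (SD 0.335) around 0. Doublets missed by the score, and contact or uptake between macrophages and other cells, stay open and were not tested.

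The 6 libraries form 10 splits into 3 against 3, so a share of splits under 0.05 cannot be had for any of these results. For genes, the real split gave 0 in monocyte/macrophages, T cells, NK cells, tumour cells and fibroblasts, which 10 of the 10 splits reached, and 1 in neutrophils, which 2 splits reached. The highest counts among the other splits were 948, 829, 316, 1454, 226 and, in neutrophils, 1202. In each class the split with the highest count set the few-kind libraries (IgG 1, anti-VSIG4 1 and anti-VSIG4 2) against the many-kind, which points to a structure of the samples. For lists, the real counts and the highest others were 14 and 19 in monocyte/macrophages (4 splits as large), 20 and 26 in T cells (4), 11 and 17 in NK cells (4), 25 and 24 in neutrophils (1), 22 and 23 in tumour cells (2), and 17 and 23 in fibroblasts (3). For abundance, 0 classes and 0 subsets passed in the real split, which 10 of the 10 splits reached, and the highest others were 3 classes, 2 T and NK subsets and 1 monocyte/macrophage subset.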
